A study of Mus musculus with 3 samples.

How the data were processed

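RNA was measured in 3 sublines of the mouse B16 melanoma line, called F0, F1 and F10, with 1 library each. Per the labels' protocols, cells grew in high-glucose medium with 8% serum, were used within 10 passages of thawing, and were harvested as subconfluent monolayers for column purification of total RNA. Polyadenylated RNA was made into libraries with a stranded mRNA kit, per the labels. The submitters' processing notes name bcl2fastq, TopHat, Bowtie2, Cufflinks and the genome build mm10, and their versions, settings and gene annotation are not given in the sources used here. The deposited table holds 1 value per gene and library in RPKM (reads per kilobase of transcript, scaled to library size), per the file headers. It also holds the authors' z scores, a score column for F1 against F0 and another for F10 against F0. For each gene with a score (13759 and 13873 genes), the authors' score equalled the RPKM difference divided by the square root of the RPKM sum, within 1e-09. It therefore carries no replicate spread.

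The table had 14313 rows. A spreadsheet date stood in place of the gene symbol in 20 of them, holding 0.174% of all RPKM, and these were left out, leaving 14293 genes. An exact 0 can be a failed estimate in such a table, so genes at 0 are described as listed at 0. Genes with an RPKM of at least 1 in at least 1 library were compared (10701 genes), as differences of log2(RPKM + 1). A fold on this scale understates differences of low genes. The group of each library came from its subclone label. Each group has 1 library, so there is no test, no p-value and no replicate error, and a difference between libraries may come from the subline, the culture or the library.

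Depth was estimated from the RPKM steps of low genes. In single-transcript genes of at least 800 bases (1392 genes), low values times transcript length, less 40 bases, gathered at the worth of 1 fragment, and 81.1% of those near the step lay within 5% of it. By these estimates, a 1 kb transcript at 1 RPKM held 5.45 fragments in F0, 6.32 in F1 and 5.39 in F10, and the median compared gene held 120, 139 and 117. Ratios of values under 0.3 RPKM in both libraries gave depths relative to F0 of 1.16 for F1 and 0.989 for F10. Fragments per gene were then estimated from RPKM and the median length of the gene's protein-coding transcripts (GENCODE M21, on GRCm38, which is mm10; 99.1% of genes had a length, 529 through an older symbol). Intervals of RPKM ratios are 95% exact Clopper-Pearson intervals from these estimated fragments. They are approximate and cover counting error only, as does the floor of 3 fragments, which for a 1 kb transcript is 0.55 RPKM in F0, 0.475 in F1 and 0.557 in F10.

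Genes differing at least 2-fold were counted by direction for each pair of libraries, genes at least 2-fold from each of the other libraries were counted per library, and genes moving the same way by at least 0.5 (log2) at each step from F0 to F1 to F10 and by at least 1 in total were counted as stepping. The number that counting error alone would give came from 100 draws of Poisson counts around each gene's mean over the 3 libraries, for the 10651 compared genes of known length. The 33 gene lists were fixed before the data were examined. A list's median difference was placed among those of 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these libraries, and lists with under 5 compared members got values only. A list is called outside the random lists when it lies below percentile 2.5 or above percentile 97.5. Lists share genes and libraries, so their percentiles are not independent.

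Named genes were chosen by a rule written before the data were examined. It takes, per pair, the 12 largest differences each way, leaving out predicted or unnamed genes, small RNAs and pseudogene symbols. It adds from each list the 4 members with the largest F10 against F0 difference and any member at least 2-fold apart in a pair, every melanoma driver, sex chromosome and cell type marker gene, and the 10 largest stepping genes each way. Genes named outside the rule are marked as such.

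Alternatives set beforehand were pseudocounts of 0.1 and 0.5, no filter, a filter at 5 RPKM, rescaling each library to the same sum (TPM scale) or by its median ratio to the geometric mean of the libraries, leaving out predicted genes, small RNAs and pseudogene symbols, thresholds of 1.5-fold and 4-fold, random lists matched on 1 library, and list means. Subtraction of the median difference of 20 GC bins, or of the 40 neighbouring genes on the chromosome, was added after seeing the data. The steps were tested on simulated data of 10651 genes, 200 of them changed. The changed genes were drawn from those averaging at least 3 RPKM over the libraries, so recovery of lower genes was not tried. Of genes changed 3-fold, 94% were recovered for F10 against F0, 95% for F1 against F0 and 97% for F10 against F1. All 100 genes changed 5-fold were recovered in each. Of unchanged genes, 0.344%, 0.211% and 0.306% lay at least 2-fold apart. Apart from the changed genes, the simulated libraries differed by counting error only. The recovery and these shares therefore do not cover variation between cultures or library preparations. Of 200 unshifted lists, 8%, 2% and 6% fell outside the random range. These lists were random draws of independently simulated genes. Their share therefore does not show how often a list of genes that vary together would fall outside. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, with figures from matplotlib 3.10.9.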

Results

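Gene expression was measured by RNA sequencing in 3 sublines of B16, a melanoma line from C57BL/6J mice. F0, F1 and F10 bear the numbers by which B16 sublines are named, and F10 is widely used as a highly lung-metastatic line obtained by repeated selection in mice. Each subline had 1 library, so no difference below has a replicate check. Depth was estimated from the table itself: a 1 kb transcript at 1 RPKM (reads per kilobase, scaled to library size) held 5.45 fragments in F0, 6.32 in F1 and 5.39 in F10. RPKM reached at least 1 for 10284 genes in F0, 10260 in F1 and 10354 in F10. Across the 10701 genes compared, log2 values correlated at a Pearson r of 0.97 for F10 and F0, 0.976 for F1 and F0 and 0.965 for F10 and F1. These are correlations across genes, which are not independent replicates.

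The comparison of F10 with F0 sets the highly metastatic subline against the parental one. Interferon-stimulated genes were lower in F10 in a block. All 31 compared members lay below their F0 value, 24 of them at least 2-fold, and the median difference was -1.37 (log2), below each of the 10000 matched random lists. Isg15, a ubiquitin-like antiviral protein, read 35.5 RPKM in F0 and 2.49 in F10, a ratio of 14.2 (95% counting interval 7.25 to 29.3). Ifit1, which binds viral RNA, read 19.2 and 1.64, and Ifi27 read 161 and 35.4. The transcription factors Irf7 (2.13 and 0.213, 2 estimated fragments in F10, a ratio of 10 with interval 2.54 to 91.3) and Irf9 (9.88 and 2.88) and the RNA sensors Ddx58 (10.8 and 2.78) and Ifih1 (4.66 and 1.47) followed the same direction, as did the chemokine Cxcl10 (24.6 and 5.31). MHC class I antigen presentation genes had a median of -0.90, again below all random lists, with 6 of 13 members at least 2-fold lower and none higher. B2m, the light chain of MHC class I, read 444 RPKM in F0 and 187 in F10, a ratio of 2.37 (2.19 to 2.58), and the peptide transporter Tap1 read 3.67 and 1.21. H2-T23 read 2.45 and 0.288 RPKM, a ratio of 8.5 (2.27 to 83.1), and H2-M3 read 2.22 and 0.132, a ratio of 16.8 (2.63 to 702). They rest on 2 and 1 estimated fragments in F10 and belong to a multigene family whose reads may be shared between copies. Leukocyte markers, which could carry such genes into a culture, summed to 3.33 RPKM in F0 and 3.39 in F10.

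**Figure D1:**
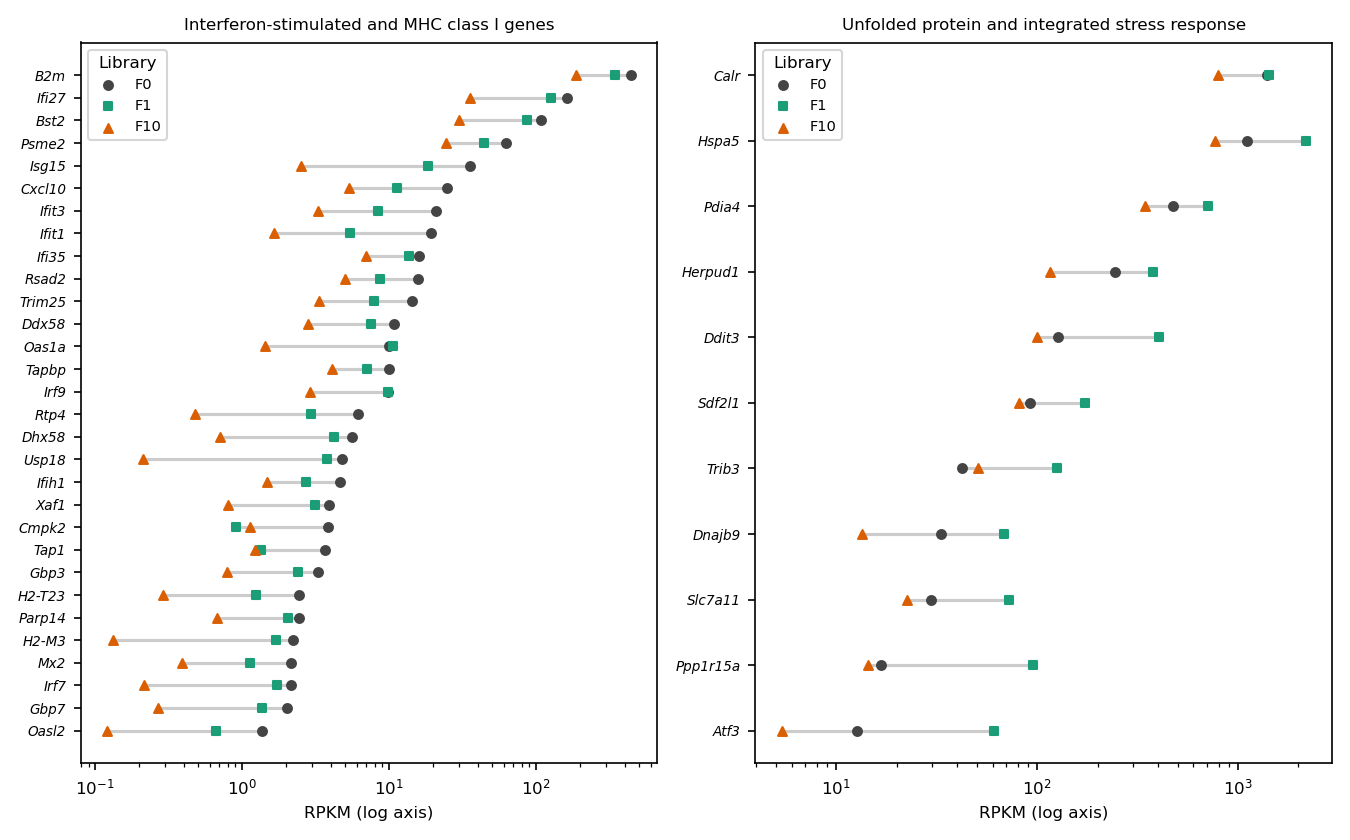
RPKM on a log axis for the named interferon-stimulated and MHC class I genes (left) and the named unfolded protein and integrated stress response genes (right), with 1 point per library for F0, F1 and F10. Each gene on the left reads lower in F10 than in F0, and on the right Ddit3 reads 404 RPKM in F1 against 126 in F0 and 100 in F10.

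Of all compared genes, 337 differed at least 2-fold between F10 and F0, 165 higher and 172 lower in F10. The balance of directions turned with the setting, with 306 higher and 223 lower on the TPM scale and 73 higher and 103 lower at a filter of 5 RPKM. After subtraction of the median of GC bins, an alternative chosen after seeing the data, 132 were higher and 166 lower. Over the 10651 genes of known length, 329 differed, where counting error alone gave 36.4 on average and 49 at most. The largest difference was Ccl5, a chemokine for T cells (chromosome 11, 83525778 to 83530518, GRCm38), at 62.9 RPKM in F0, 7.55 in F1 and 1.77 in F10. Its F0 to F10 ratio was 35.4 (14 to 104). Some other genes of secreted or surface proteins of immune contact were also lower, among them Lgals9 (84.9 to 26.5), Il18 (4.95 to 1.74), Tgfb1 (6.86 to 2.88) and Raet1e, a ligand of the NKG2D receptor (12 to 0.935). The checkpoint ligand Cd274 (2.61 to 0.829) was lower by 0.98 on the log2(RPKM + 1) scale, just short of 2-fold. Raet1e belongs to a family of near-identical genes and is uncertain. The list of immune ligands had 5 of 17 members at least 2-fold lower and none at least 2-fold higher, with 8 members above their F0 value and 9 below. Its median of -0.12 lay within the random lists while its mean of -0.62 lay outside them. Without the filter on low values the median was 0.03, also within them. Osteopontin, encoded by Spp1, read 19.2 and 1.5, the small heat shock protein Hspb1 read 17.3 and 1.46, the junction protein F11r read 15.1 and 1.67, and the actin-bundling protein Fscn1 read 8.25 and 1.2. Hapln4 (6.94 to 0.0527) had an F0 to F10 ratio of 132 (23.7 to 5348) on 1 estimated fragment in F10. Abcc2 (6.09 to 0.105) had a ratio of 58 (18.2 to 265) on 3, and Tagln2 (9.45 to 0.409) a ratio of 23.1 (5.81 to 1405) on 1.

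Among genes higher in F10, Mcoln3, a lysosomal cation channel (chromosome 3, 146117450 to 146141806, GRCm38), read 0.98 RPKM in F0 and 27 in F10, a ratio of 27.5 (14.3 to 61.2). Tmsb4x, the actin-sequestering thymosin beta 4 that has been linked to metastasis, read 0.835 and 19.1, a ratio of 22.9 (8.33 to 125) that rests on 3 estimated fragments in F0. Isyna1 and Mgarp were listed at 0 in F0 and at 9.33 and 8.23 RPKM in F10. Jph2, a junction protein of muscle, was listed at 0 in F0 and at 4.01 RPKM in F10, and belongs to a skeletal muscle list drawn up after the values were seen. Without the 6 genes that prompted that list, 27 of its 34 genes in the table read higher in F10 than in F0 and 5 lower, with a median of 0.23. Mid1 (0.708 to 10.7), Hspb8 (0.515 to 8.84), Ddah2 (0.418 to 6.86, a ratio of 16.4 with interval 4.87 to 76.3 on 3 fragments in F0), Pla2g2e (11.4 to 66.2) and Fstl1 (1.45 to 11.3) were also among the 12 largest, with Art5 (0.893 to 8.98) and Arl11 (2.39 to 15.9). The metastasis-linked list had 5 of 20 members at least 2-fold higher in F10 and 1, Spp1, at least 2-fold lower. Its median of -0.08 lay inside the random lists, its mean was 0.07, and 9 members lay above their F0 value and 11 below. Besides Tmsb4x, the higher members were Met, the receptor of hepatocyte growth factor (81.2 to 192, a ratio of 2.36, interval 2.2 to 2.53), fibronectin Fn1 (3.39 to 7.99), S100a6 (2.33 to 7.34) and Cd82 (1.97 to 4.95). S100a6 had a ratio of 3.14 (1.31 to 8.81) on 7 estimated fragments in F0. Cd82 only just reached 2-fold on the log2(RPKM + 1) scale, with a ratio of 2.51 (1.07 to 6.64) on 8. The list was counted without regard to whether a member promotes or opposes metastasis, so the tally does not show a shift toward metastasis. Integrin beta 5, Itgb5, read 2.61 and 8.44, while the 9 compared integrins had a median of -0.10 and a mean of 0.12.

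In total 9 of the 25 lists with enough members lay outside the random lists for F10 against F0. Besides the interferon and MHC lists, those lying low were melanocyte differentiation and pigment genes (median -0.30, percentile 0.43), proteases and their inhibitors (-0.30, percentile 0.12), lysosomal genes (-0.28, percentile 0.41) and cell-cell adhesion genes (-0.24, percentile 2.25). Pigment genes included Pmel, the fibril protein of melanosomes (2714 RPKM in F0 and 1669 in F10), and Cited1 (84.9 and 31.4), while the melanocortin receptor Mc1r read 37.9 and 57.5. Cathepsin B, Ctsb, read 240 and 90.9.  Those lying high were glycolysis and hypoxia genes (0.20, percentile 99.985), cholesterol and fatty acid synthesis genes (0.15, percentile 99.9) and extracellular matrix genes (0.23, percentile 98.1). Of the glycolysis and hypoxia genes, the lactate transporter Slc16a3 read 6.81 and 25.4, while Ero1l was lower, at 136 and 62.8.  Fibroblast markers were also higher in F10: Pdgfrb read 0.758 and 3.34, and Dcn, itself on the matrix list, read 0.396 and 2.62. Both reached 1 RPKM in F10 alone, so the filter fixed their direction. Pdgfrb is also on the list of dedifferentiated and neural crest genes. Postn read 2.94 and 4.2, a ratio of 1.43 whose counting interval (0.989 to 2.13) includes 1. Without the filter on low values the protease median was 0.00134 and the adhesion median of -0.09 lay inside the random lists, as did the matrix median of 0.11 at a filter of 5 RPKM. The pigment (-0.24), lysosomal (-0.21), protease (-0.15) and matrix (0.17) lists lay inside when means were taken in place of medians.

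**Figure D2:**
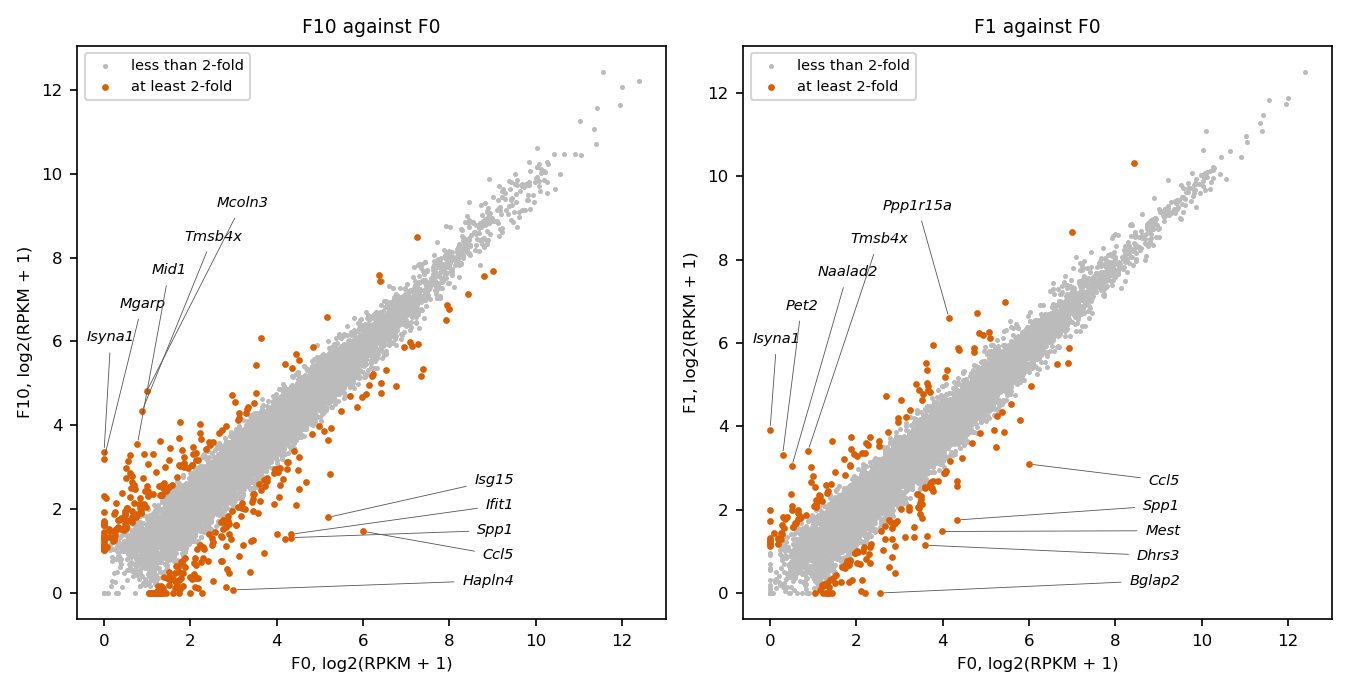
log2(RPKM + 1) of each of the 10701 compared genes in F0 (horizontal) against F10 (left) or F1 (right), 1 library each, with genes at least 2-fold apart in colour. They number 337 on the left and 213 on the right, and the largest differences are named.

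The comparison of F1 with F0 sets the subline next in number against the parental one. The clearest block was the unfolded protein and integrated stress response, which was higher in F1. All 21 members lay above their F0 value, 6 at least 2-fold, and the median was 0.75, above all random lists. Ddit3, a stress-induced transcription factor, read 126 RPKM in F0 and 404 in F1, a ratio of 3.2 (2.86 to 3.59). Atf3 read 12.6 and 60.9, the phosphatase subunit Ppp1r15a 16.7 and 95.9, Trib3 42.4 and 125, the cystine transporter Slc7a11 29.8 and 72.8 and the chaperone Hspa5 1103 and 2175. Outside that list, Gadd45a (11.3 and 45.1), Nupr1 (26.8 and 104), Nfil3 (5.43 and 25.4) and the haem-degrading enzyme Hmox1 (344 and 1283) were also higher. In F10 Hmox1 read 139 RPKM, Ddit3 100, Trib3 50.7 and Nupr1 35.2.

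At least 2-fold differences between F1 and F0 numbered 213, with 104 higher and 109 lower in F1, 106 higher and 102 lower after division by median ratios, and 154 higher and 213 lower with a pseudocount of 0.5. Over the genes of known length, 209 differed, against a mean of 31.1 and a maximum of 44 from counting error alone. Isyna1, listed at 0 in F0, read 14.1 RPKM in F1, and Tmsb4x read 9.57, against 3 estimated fragments in F0. Naalad2 read 0.416 in F0 and 7.21 in F1, Basp1 1.71 and 11.5, and Pet2 0.223 and 8.93. The largest difference downward was again Ccl5, with an F0 to F1 ratio of 8.33 (5.49 to 13.8), followed by Spp1 (19.2 to 2.37). Mest (14.7 to 1.78), Dhrs3 (11.1 to 1.22), Emilin1 (11.4 to 1.57), Igf2bp3 (6.13 to 0.811) and Gstk1 (9.02 to 1.55) were lower. Crabp2 (5.8 to 0.534), Olfml1 (3.41 to 0.244) and the phosphatase Ptprb (3.33 to 0.0269) rested on 3, 3 and 2 estimated fragments in F1, with F0 to F1 ratios of 10.9 (3.34 to 55.6), 14 (3.74 to 61.2) and 124 (27 to 825). Sncg read 3.57 RPKM in F0, on 16 estimated fragments, and was listed at 0 in F1. Bglap2 read 4.84 in F0, on 11 estimated fragments, and under 0.001 in F1. That level was treated as 0 and may likewise be a failed estimate. For this pair 12 of 25 lists lay outside the random lists. Lying low were cholesterol and fatty acid synthesis (median -0.43), cell cycle (-0.33) and interferon-stimulated genes (-0.34, 4 of 31 at least 2-fold lower), each below all random lists. MHC class I (-0.40), pigment (-0.31), p53 target (-0.29), Wnt, Notch and YAP target (-0.29), metastasis-linked (-0.28), immune ligand (-0.24), glycosyltransferase (-0.18) and nuclear oxidative phosphorylation genes (-0.16) also lay low. Trpm1, a melanocyte channel, read 118 in F0 and 44.6 in F1, and Cdkn1a, the p53 target p21, read 155 and 83.3. Under at least 1 alternative the Wnt, Notch and YAP list (-0.07 without the filter on low values) and the glycosyltransferases (-0.15 when means were taken) lay inside the random lists.

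**Figure D3:**
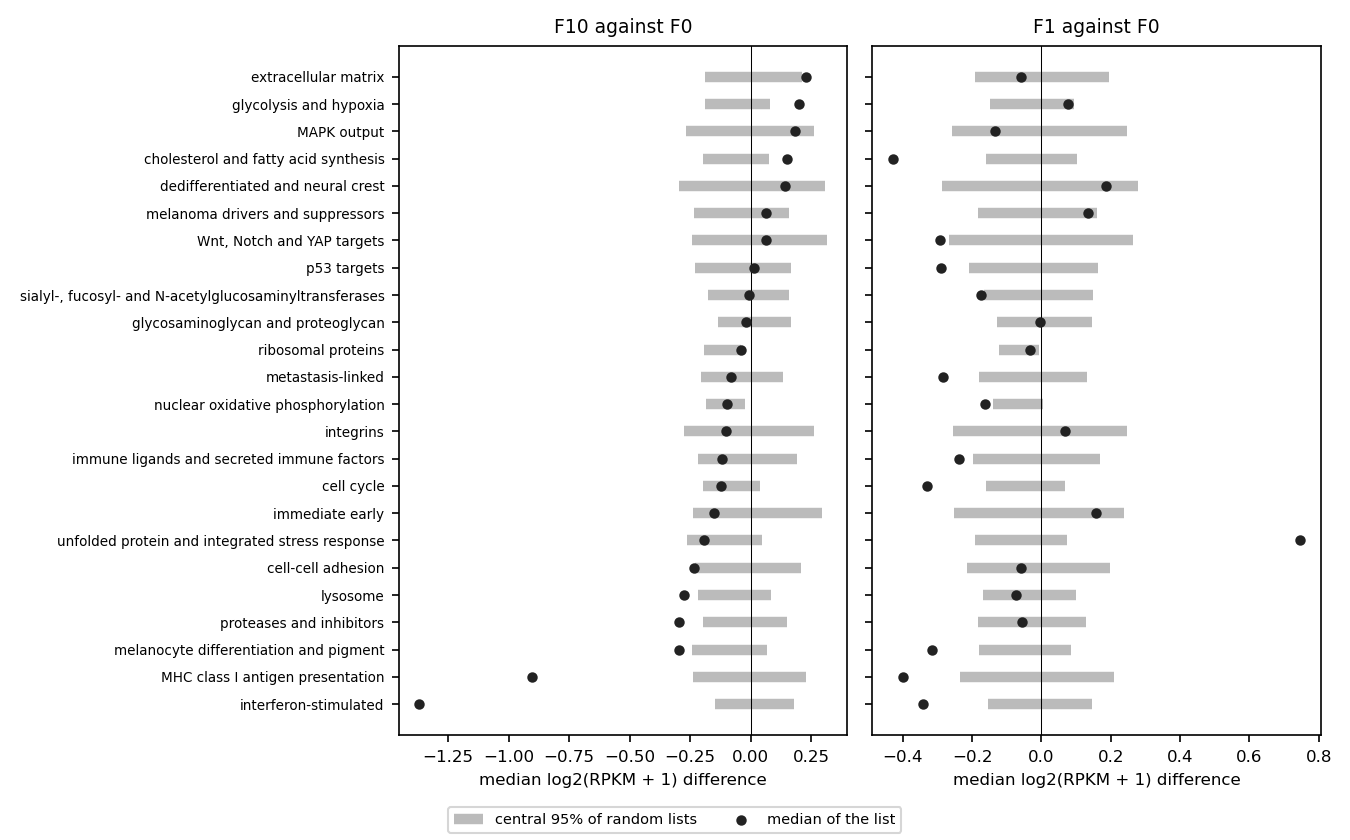
Median log2(RPKM + 1) difference of each list shown, with at least 5 compared members (points), for F10 against F0 (left) and F1 against F0 (right), over the central 95% of 10000 matched random lists (grey bars). The interferon-stimulated list sits at -1.37 on the left and the stress response list at 0.75 on the right.

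The comparison of F10 with F1 sets the highly metastatic subline against the subline next to F0 in number. The stress response genes were lower in F10 than in F1 (median -0.92, 10 of 21 at least 2-fold), as were the interferon-stimulated (-0.93, 14 of 31) and MHC class I genes (-0.63, 1 of 13). Cholesterol and fatty acid synthesis genes were higher in F10 by a median of 0.61, with 6 of 28 at least 2-fold, including fatty acid synthase Fasn (27.7 in F1 and 71 in F10), Lss (14.4 and 35.7) and Acat2 (25.8 and 63.1). Cell cycle genes were higher by a median of 0.22, with none of 36 at least 2-fold. Genes at least 2-fold apart numbered 426, with 221 higher and 205 lower in F10. The balance turned with the setting, with 414 higher and 273 lower on the TPM scale, 119 and 142 at a filter of 5 RPKM, and 171 and 200 after subtraction of the median of GC bins, an alternative chosen after seeing the data. Over the genes of known length, 424 differed, where counting error alone gave 31.9 on average and 47 at most. The largest single differences were Tagln2, at 31.3 RPKM in F1 and 0.409 in F10 on 1 estimated fragment, a ratio of 76.6 (20.2 to 4546), and Gsta4, a glutathione transferase, at 2.51 and 42.3, a ratio of 16.8 (9.63 to 32.3). Hs3st1 (12.4 and 0.783), Tubb2b (20.2 and 1.38) and Ippk (31 and 4.58) were lower in F10, and Raet1a read 5.47 in F1 and under 0.001 in F10, in a family of near-identical genes. Emilin1 (1.57 and 19.2), Gstk1 (1.55 and 14.4), Slc44a3 (1.19 and 11.1) and the muscle myosin light chain Myl1 (1.18 and 9.62) were higher, and Galnt6, listed at 0 in F1, read 3.84 in F10. In all 13 of 25 lists lay outside the random lists for this pair. The others lying high were extracellular matrix (0.32), MAPK output (0.39), metastasis-linked (0.19), glycosaminoglycan and proteoglycan (0.17), glycolysis and hypoxia (0.15) and nuclear oxidative phosphorylation genes (0.09), and those lying low were immediate early (-0.29) and lysosomal genes (-0.20). Against F0, the stress response median was 0.75 in F1 and -0.19 in F10, cholesterol and fatty acid synthesis -0.43 and 0.15, and cell cycle -0.33 and -0.12. Metastasis-linked genes lay at -0.28 and -0.08, so for these lists F1 lay further from F0 than F10 did. F10 lay further for others, such as interferon-stimulated (-0.34 and -1.37), MHC class I (-0.40 and -0.90) and matrix genes (-0.06 and 0.23). Fibroblast markers, of which Dcn is also on the matrix list, were higher in F10 than in F1 as well, with Pdgfrb at 0.148 in F1 and 3.34 in F10. Pdgfrb and Dcn reached 1 RPKM in F10 alone, so here too the filter fixed their direction. Without the filter on low values the immediate early median was 0.04. Under at least 1 alternative the matrix (0.02), MAPK output (0.04), metastasis-linked (0.13), lysosomal (-0.17), proteoglycan (0.04) and glycolysis and hypoxia (0.06) lists lay inside the random lists. Genes of high GC content read higher in F10 than in F1, by a median of 0.21 in the highest of 8 GC bins against -0.15 in the lowest. For F10 against F0 the trend had the same direction, at 0.16 in the highest bin and -0.08 in the lowest. The bins held 680 or 681 genes each and so did not cover all of the compared genes.

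F10 stood apart from both other libraries in 151 genes, 81 higher and 70 lower, F1 in 92 (51 and 41) and F0 in 61 (34 and 27). Counting error alone gave means of 8.53, 7.78 and 8.92 over the genes of known length. Stepping from F0 through F1 to F10 was seen in 73 genes, 32 upward and 41 downward, against a mean of 5.87 from counting error over the genes of known length. The counting error draws gave all libraries the same mean, and other orders of the libraries were not counted. The number of stepping genes therefore does not test the order. More genes differed at least 2-fold between F10 and F1 (426) than between F10 and F0 (337). Some genes, such as Mcoln3 and Ccl5, are counted both as stepping and as apart. Upward were Mcoln3 (0.98, 5.99 and 27 RPKM in F0, F1 and F10), Tmsb4x, Mgarp, Ddah2, Pla2g2e, the collagen chaperone Fkbp10 (1.19, 2.61 and 8.98), Hoxb9 (1.04, 2.5 and 7.47) and Lhfp (1.87, 4.45 and 10). The muscle genes Ckm (0.527, 1.47 and 6.26) and Tnni2 (0.559, 2.4 and 5.93) also stepped upward, Tnni2 on 2 estimated fragments in F0, and belong to the skeletal muscle genes that read higher in F10. Downward were Ccl5, Isg15, Ifit1, Ifit3, Rtp4, Igtp, Hapln4, Hspb1, Abcc2 and Rab29, a small GTPase at 36.6, 10.4 and 6.17 RPKM.

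None of the 14 compared melanoma drivers and suppressors differed 2-fold in any pair, and their median was 0.06 for F10 against F0. Braf read 5.65, 7.3 and 6.57 RPKM in F0, F1 and F10, Nras 21.7, 24.2 and 22.3, and Trp53 55.9, 59.4 and 51.7. Of the other lists inside the random lists for F10 against F0, 1 is not used here. Medians of the rest were 0.14 for dedifferentiated and neural crest genes, 0.18 for MAPK output, 0.06 for Wnt, Notch and YAP targets, 0.01 for p53 targets, -0.01 for glycosyltransferases and -0.02 for glycosaminoglycan and proteoglycan genes. Medians were -0.04 for ribosomal proteins, whose reads may be shared with pseudogenes, -0.10 for nuclear oxidative phosphorylation, -0.12 for cell cycle, -0.15 for immediate early genes and -0.19 for the stress response. On the TPM scale the medians of glycosyltransferases (0.07), glycosaminoglycan and proteoglycan genes (0.05) and ribosomal proteins (0.03) were above 0. Means had the other sign for p53 targets (-0.21), glycosaminoglycan and proteoglycan genes (0.03) and immediate early genes (0.08). The p53 targets lay outside the random lists, at a median of -0.22, after subtraction of GC bins. At a filter of 5 RPKM the metastasis-linked list (-0.26) lay outside, as did the stress response (-0.29) and ribosomal proteins (-0.02) by their means, and MAPK output (0.34) after subtraction of neighbouring genes. In lists too small to place, the chemokine receptor Ackr3 read 1.37, 0.157 and 0.278 RPKM, on 13, 2 and 3 estimated fragments. The 4 compared histone genes had a median of -0.43 and a mean of -0.11, with 1 above its F0 value and 3 below. No listed sex chromosome or mitochondrial genome gene was among the genes compared. No endothelial or epithelial marker reached 1 RPKM, and the leukocyte markers Lyz2 (1.23, 1.37 and 1.78) and Cd68 (2.09, 2.06 and 1.21) stayed near the floor.

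In the authors' deposited table, the largest score for F10 against F0 was that of the ferritin light chain Ftl1 (27.1), named here after its values were seen, followed by Pmel (-15.8) and Calr (-12.9), and for F1 against F0 those of Hmox1 (23.3), Hspa5 (18.7) and Ddit3 (12.1). A size of 2 was passed by 461 genes for F10 against F0 and 371 for F1 against F0. The score grows with expression, and of the 100 largest by size, 29 and 23 genes differed at least 2-fold.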

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

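Each result rests on 1 library per subline, and alternatives change only how those libraries are read. Subtraction of GC bins and of neighbouring genes was chosen after seeing the data. No paired analysis was possible because each subline has 1 library. In the order F10 against F0, F1 against F0 and F10 against F1, the counts of genes at least 2-fold apart were 638, 543 and 827 with a pseudocount of 0.1, and 367 for F1 against F0 with 0.5. They were 176, 132 and 261 with a filter at 5 RPKM, where fewer genes were compared, and 529, 416 and 687 on the TPM scale, where the pseudocount of 1 is smaller relative to the values. They were 1318, 1092 and 1655 at 1.5-fold, and 44, 19 and 40 at 4-fold. Genes apart from both other libraries, for F0, F1 and F10, numbered 178, 239 and 323 with a pseudocount of 0.1, 102, 157 and 227 with 0.5, 123, 182 and 265 on the TPM scale, 293, 490 and 639 at 1.5-fold and 5, 6 and 17 at 4-fold. A filter at 5 RPKM gave 33 for F0 and 81 for F10. Stepping genes numbered 161 with a pseudocount of 0.1, 123 on the TPM scale and 45 with a filter at 5 RPKM. The remaining 68 counts stayed within 1.5 times. The number of lists outside the random lists stayed within 1.5 times under every alternative run. Of the single list medians, 762 kept their side of the random range, 36 fell inside it and 22 moved outside it. Of medians outside the range, 2 changed sign, without the filter on low values: the proteases for F10 against F0 (0.00134) and the immediate early genes for F10 against F1 (0.0369); the cause was not tested. Of medians inside the range, 45 of 448 values under alternatives changed sign, and the p53 targets for F10 against F0 did so while moving outside the range (-0.22 after GC bins). Of the counts by direction, 29 moved by over 1.5 times and 37 did not. The larger direction turned: F10 was higher than F0 in 306 genes and lower in 223 on the TPM scale, and in 73 and 103 at a filter of 5 RPKM. For F1 against F0 they were 229 and 314 with a pseudocount of 0.1, 154 and 213 with 0.5, and 106 and 102 after division by median ratios. For F10 against F1 the numbers were 414 and 273 on the TPM scale, 119 and 142 at that filter, and 171 and 200 after GC bins. Depth limits genes near 1 RPKM most, since a 1 kb transcript at that level holds 5.45 estimated fragments in F0.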

Other observations

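The tests and gene lists of this part were chosen after the results were seen. Of a list of 46 skeletal muscle genes, 40 are in the table, 6 of which prompted the list. Of the other 34, with no filter, 27 read higher in F10 than in F0, 8 of them at least 2-fold, and 5 lower, with a median of 0.23. The values included fast myosin Myh4 (0.632, 0.876 and 4.61 RPKM in F0, F1 and F10), the calcium pump Atp2a1 (0.867, 1.35 and 5.7), parvalbumin Pvalb (0.62, 0.71 and 5.01) and skeletal actin Acta1 (3.15, 3.57 and 10.2). Glutathione transferases had a median of -0.14 for F10 against F0, within the random lists, and -0.22 for F1 against F0, at percentile 1.2. Hypoxia genes taken without glycolysis had a median of 0.11 for F10 against F0, inside the random lists.

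The muscle pattern was weighed without the genes that prompted the list (Ckm, Tnni2, Mb, Jph2, Tnnt3 and Myl1) and without those, 10 of the 20 compared, that reached 1 RPKM in F10 alone, since the filter fixed their direction. The 6 genes left, a small part of the list, read higher in F10, 4 of them at least 2-fold, with a median of 1.29 (random lists -0.32 to 0.40). It was 1.25 after subtraction of GC bins and 1.14 after subtraction of neighbouring genes, which argues against GC content or chromosome position as the whole cause. Fibroblast markers also read higher in F10 in 7 of 7 listed, summing to 4.47 RPKM in F0 and 12 in F10. Of these, 2 (Pdgfrb and Dcn) differed at least 2-fold on the log2(RPKM + 1) scale. Col3a1, Lum and Pdgfra rested on 0 estimated fragments in F0 and 2 in F10. The counting interval of the Postn ratio (0.989 to 2.13) included 1. RNA of mature muscle from outside the F10 culture may be a source and cannot be told apart from expression by the cells, since the ratio of adult fast to developing muscle genes in F10 (106, from 43.4 and 0.41 RPKM) compares sets drawn up after their levels were known.

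Expression differences between sublines were shared along chromosomes. For F10 against F0 the chromosome medians ran from -0.32 on chromosome 14 and -0.25 on chromosome 13 to 0.17 on chromosome 12 and 0.21 on chromosome 7. Their SD over 20 chromosomes was 0.126, against at most 0.0316 in 1000 shuffles of gene places, and 0.116 after subtraction of GC bins, which argues against chance order and against GC content as the whole cause. Medians of the lower- and higher-expressed genes went together across chromosomes (r = 0.953, at most 0.711 in shuffles), so a difference in DNA copy number between sublines is a candidate explanation. DNA was not measured here, and regulation along whole chromosomes would give the same values.

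The lower interferon-stimulated genes of F10 were set against 3 explanations. Leukocytes in the F0 culture would bring their own transcripts, but leukocyte markers summed over F0 minus F10 differed by -0.061 RPKM where B2m differed by 257. Single markers moved both ways, with Cd68 lower in F10 (2.09 to 1.21 RPKM) and Lyz2 higher (1.23 to 1.78). The whole sum in F0 was 3.33 RPKM. After subtraction of neighbouring genes the list median was -1.55, which argues against position on chromosomes with lower expression in F10. The state of the culture at harvest and a lasting property of the subline cannot be told apart with 1 library of F10, and either could give the pattern.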
